A study of Mus musculus with 9 samples.

How the data were processed

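Bulk RNA-seq was performed on RORγt-positive cells from C57BL/6 mice carrying Runx3-tdTomato and RORgt-EGFP reporters. Per the labels, fractions sorted from fetal liver at embryonic day 14.5 were cultured for 10 to 12 days on TSt4/DLL4. This stromal cell line presents the Notch ligand DLL4, and IL-7 and SCF were added at 20 ng/ml each. RORγt-positive cells were then sorted again and labelled Runx3-positive or Runx3-negative. Libraries were made from 50 to 200 cells with the SMART-Seq HT PLUS kit, which amplifies full-length cDNA from polyadenylated RNA and does not mark strand, so antisense and overlapping genes are uncertain. Groups were taken from the cell type label, which gives Runx3-positive (n = 5) or Runx3-negative (n = 4). No label says that the samples came from separate animals or cultures, so p-values measure the spread between these samples, which may be partly technical. The mean of 4 Y-linked genes was 3.66 and 3.59 in Runx3-positive replicates 1 and 2, and 9.72 to 10 in replicates 3 to 5. It was 5.12 in Runx3-negative replicate 2 and 8.995 to 10.39 in the others. These values argue against a single pool of cells behind each population, but the number of separate sources stays unknown.

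Per the submitters' processing notes, fastp, HISAT2 and featureCounts were used with the mouse build GRCm39, and versions, annotation and the step from counts to expression values are not given in the sources used here. The values deposited by the authors were on a logarithmic scale, taken here as log2, with 1 column per library, from -2.15 to 17.24. The base was inferred, since 2 raised to the values summed to between 13900000 and 15300000 per library, whereas e raised to them summed to between 621000000 and 758000000. Totals of normalised values can be arbitrary, so this does not settle the base, and all folds and linear values rest on it. Genes with no signal in any library were listed at 0, and some other genes had values below 0. Shrinkage of low values towards the mean of the gene, as in a regularised logarithm, is possible, but no such step is given in the sources used here. If it was used, differences of genes with few reads are understated, and their SDs may be too small. Whole reads could not be recovered and read depth is unknown, so no counting interval or floor is given. The table held 55061 entries, of which 1 had a blank name, stood at 0 and was left out. Of 55060 named genes, 28609 were listed at 0 in all 9 libraries and 26451 were not. Of 20 housekeeping genes looked for, 19 were in the table and 0 of these were at 0. Gapdh was the lowest of them, at 6.62 to 8.13, and the cause was not tested.

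The planned test assumed normalised counts to be put on a log2 scale with a pseudocount of 1, and because the values were already logarithmic they were used as deposited. Genes with a linear value of at least 10, a log2 value of 3.32, in at least 4 libraries were kept, which left 13329. Differences were tested with limma 3.58.1 in R 4.3.3 (empirical Bayes with trend and robust settings, two-sided, without covariates), with Benjamini-Hochberg adjustment and a threshold of 0.05. Single values were tested by exact permutation over all 126 splits. The 31 gene lists were fixed before the data were examined, and the 28 with at least 5 tested members were tested with camera from limma at a preset correlation of 0.01, adjusted over the lists. Calls of 5 of the 6 higher and 3 of the 6 lower lists held with an estimated correlation. Counts of list members given below cover tested members only, and many lists held others at 0 or below the filter. Some genes belong to several lists, so the list results are not independent.

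Genes were named by a rule also fixed before the data were examined. It took Runx3, Rorc, Il7r and Cd3e, then the 8 largest increases and 8 largest decreases past the threshold with a mean of at least 50 in the higher group and no overlap, leaving out predicted genes, pseudogenes and receptor segments. It also took up to 2 members that rose and 2 that fell with the smallest p in each list, and the 2 most abundant members of the lists of other cell types. C1qa, the stromal genes other than Timp3, Cald1 and Pdgfrb, and Cd3d, Cd3g, Trbc1, Trbc2 and Myb were named after their values had been seen. No coordinates are given, because the reference used here for gene types was of another build.

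The procedure was checked on simulated values for 13329 genes with 200 changed ones, in the same 5 against 4 design. It recovered 6% of genes changed by a log2 difference of 0.5, 24% at 1, 64% at 2 and 86% at 4, with 4 false among 94 calls. In the data 4967 genes were called, which makes the adjusted threshold less strict, so these shares may not hold there. A raised list was called and 0 of 30 unchanged lists were. Genes were simulated as independent, so this check does not cover lists whose members are correlated. The alternatives tried were other pseudocounts, filters and scalings, library weights, covariates, a block for replicate number, leaving out libraries, and other list tests. Figures were drawn with matplotlib 3.10.9.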

Results

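Transcript levels were measured by bulk RNA-seq in RORγt-positive lymphoid cells of the mouse that had been grown in culture from fetal liver progenitors and sorted by a Runx3 reporter. RORγt, encoded by Rorc, is the transcription factor that defines group 3 innate lymphoid cells (ILC3), and Runx3 is a transcription factor of innate and cytotoxic lymphocytes. The 9 libraries comprised 5 of Runx3-positive cells and 4 of Runx3-negative cells, each made from 50 to 200 cells that were positive for CD45 and RORγt and negative for surface CD3 and CD19. Runx3-positive replicates 1 to 4 came from cultures started with the RORγt-mid fraction, and replicate 5 from a fraction that was Runx3-positive but negative for CD127 and RORγt. All 4 Runx3-negative libraries came from a CD127-positive fraction negative for Runx3 and RORγt. Replicate 5 thus shared a RORγt-negative start with them, but no starting fraction gave libraries of both populations. Read depth per library is not given in the sources used here. The values were taken as log2 expression levels, and 2 raised to these values summed to between 13900000 and 15300000 per library. Values below are means ± SD, with n = 5 for Runx3-positive and n = 4 for Runx3-negative cells, and every difference is Runx3-positive minus Runx3-negative on the log2 scale.

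The comparison asked how RORγt-positive cells sorted as positive or negative for the Runx3 reporter differed. Runx3-positive cells carried high levels of the type 3 cytokine transcripts Il22 (11.42 ± 1.32 against 2.99 ± 0.08) and Il17f (12.50 ± 1.17 against 3.64 ± 0.22) and of the interleukin-1 receptor Il1r1 (11.54 ± 0.35 against 3.31 ± 0.19). Runx3-negative cells carried those of early T cell development, among them the recombination gene Rag2 (11.65 ± 0.29 against 1.99 ± 0.48), the pre-T cell receptor chain Ptcra (11.48 ± 0.15 against 1.75 ± 0.58), Cd8a (12.18 ± 0.81 against 2.16 ± 0.62) and Cd3e (11.50 ± 0.39 against 1.76 ± 0.58). Of 13329 genes tested, 2739 were higher and 2228 lower in Runx3-positive cells at an adjusted p below 0.05 in limma. The balance of higher and lower genes turned with quantile normalisation, which gave 2510 higher and 2601 lower genes, and was 2570 against 2419 with trimmed-mean rescaling. A difference of at least 2-fold was reached by 2017 of the higher and 1416 of the lower genes, and one of at least 8-fold by 792 and 495.

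Runx3 itself, which checks the sort, was at 10.24 ± 0.37 in Runx3-positive and 7.53 ± 0.47 in Runx3-negative cells, a difference of 2.71 ± 0.26 (SE; adjusted p = 6.93e-06, limma). The exact two-sided permutation test gave p = 0.0159, the smallest that the 126 splits of 5 against 4 libraries allow. Rorc was high in both populations, at 15.49 ± 0.52 and 14.88 ± 0.51, and its difference of 0.61 ± 0.28 (SE) was not past the threshold (adjusted p = 0.110, limma; exact permutation p = 0.0635). The Rorc difference was 0.38 without Runx3-positive replicate 1 and 0.36 without Runx3-negative replicate 2. Il7r, the interleukin-7 receptor chain CD127, was higher in Runx3-positive cells, at 13.65 ± 0.29 against 10.27 ± 1.10 (adjusted p = 3.87e-05, limma).

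**Figure D1:**
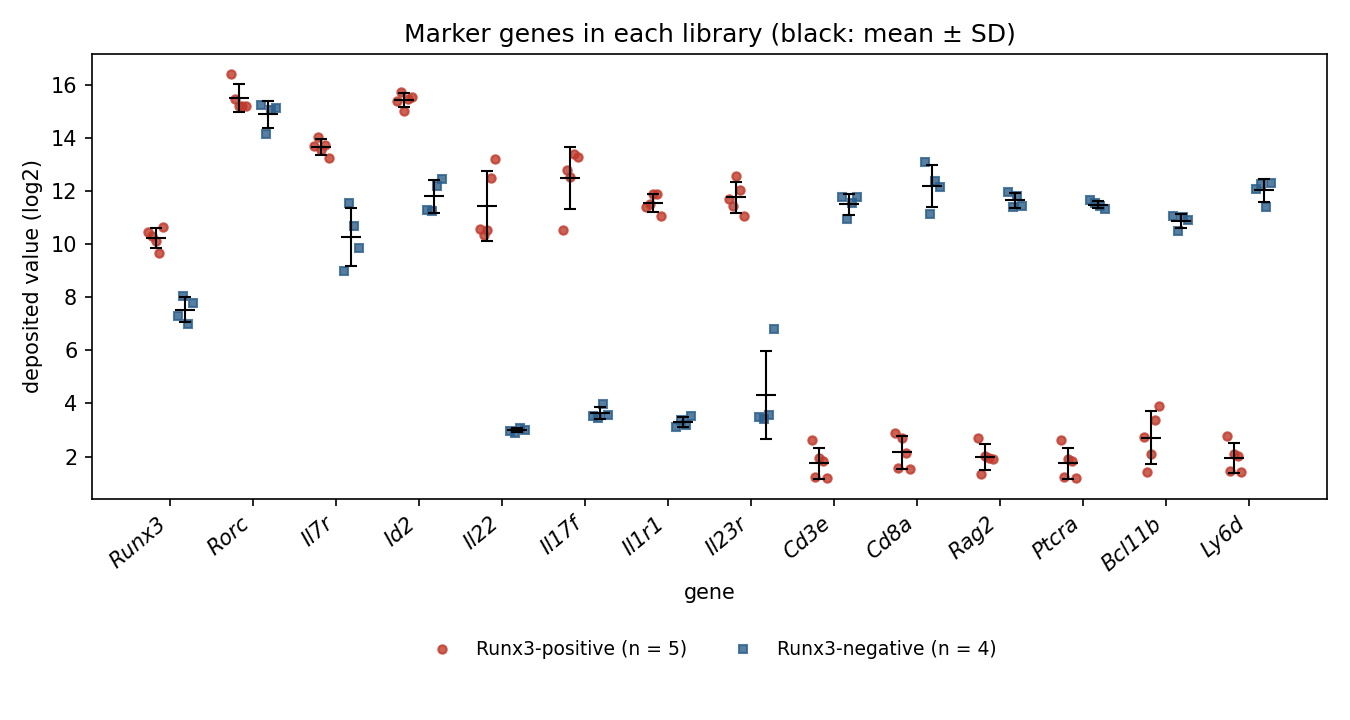
Deposited log2 values of 14 genes in each library, with Runx3-positive libraries as circles (n = 5), Runx3-negative libraries as squares (n = 4), and the mean ± SD in black. The groups overlap for Rorc and lie apart for Il22, Il17f and Il1r1, which were higher, and for Cd3e, Cd8a, Rag2, Ptcra and Ly6d, which were lower in Runx3-positive libraries.

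The largest increases in Runx3-positive cells were those of Il17f (8.86), Il22 (8.44), the chromatin protein gene Hmgn3 (8.28), Il1r1 (8.23), the NK receptor gene Klrb1b (8.21), the potassium channel gene Kcnk1 (8.16), the matrix protein gene Chad (8.0) and Igfbp7 (7.87). Their adjusted p ranged from 9.65e-10 for Il1r1 to 1.52e-06 for Igfbp7 in limma. Klrb1b shares sequence with other genes of its family, so its level is uncertain. The largest decreases were those of Ly6d (-10.06), Cd8b1 (-10.05), Arpp21 (-10.03), Cd8a (-10.02), the signalling adaptor gene Sh2d1a (-9.90), Cd3e (-9.74), Ptcra (-9.73) and Rag2 (-9.66), with adjusted p from 3.41e-09 for Arpp21 to 3.98e-08 for Cd8b1 in limma. How the deposited log2 values were made from reads is not given in the sources used here. If low values were shrunk towards the mean of each gene, as in a regularised logarithm, these differences would be understated where a group had few or no reads. The small SDs of low groups would then not show precise measurement, such low levels need not be expression, and p-values in limma could be affected.

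Genes of ILC3 and lymphoid tissue inducer cells were higher in Runx3-positive cells. Among 24 receptors and regulators of these cells, 20 rose, 1 fell and 3 did not pass, with 20 rising and 2 falling when adjusted over the list alone. The membrane protein gene Tmem176a rose from 8.23 ± 0.06 to 13.70 ± 0.31 and the interleukin-23 receptor gene Il23r from 4.31 ± 1.66 to 11.76 ± 0.58. The member that fell was Nrp1 (-0.84), whose adjusted p in limma went from 0.0170 to 0.0505 without Runx3-negative replicate 1. The list median was 3.53 and the list stood above other genes in camera (adjusted p = 1.81e-10, and adjusted p = 0.0200 with an estimated correlation). All 10 tested type 3 cytokines and lymphotoxins rose, also when adjusted over the list alone, with a median of 3.54 (camera adjusted p = 2.89e-07, and adjusted p = 0.0152 with an estimated correlation). The lymphotoxin gene Lta went from 8.54 ± 0.53 to 13.99 ± 0.39, while Il17a was listed at 0 in all 9 libraries. Of 24 myeloid and dendritic cell genes, 6 were listed at 0 in all libraries and only 10 were tested, of which 8 rose. Lyz2 was higher by 2.86 and the macrophage gene C1qa, named after its value had been seen, by 3.69. Whether these are linked to the ILC3 genes was not tested.

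Among 17 genes of ILC precursors, 11 rose, 2 fell and 4 did not pass, and 12 rose and 2 fell when adjusted over the list alone. Some of these genes, such as Id2, are also in the list of ILC3 receptors and regulators. Id2, an inhibitor of E proteins needed by innate lymphoid cells, rose from 11.79 ± 0.62 to 15.42 ± 0.26, and the integrin gene Itgb7 rose by 1.93. Ets1 fell by 1.26 and Tcf7 by 0.59. The adjusted p of Tcf7 in limma was 0.0340 with all libraries, and lay between 0.0581 and 0.0992 without any one of Runx3-positive replicates 1, 4 and 5 and Runx3-negative replicates 1 and 3. The list median was 1.88 (camera adjusted p = 0.00467, and adjusted p = 0.230 with an estimated correlation). Of 29 NK and ILC1 genes, 16 were tested. Of the 16, 10 rose, 4 fell and 2 did not pass, the same counts as when adjusted over the list alone. The Fc receptor gamma chain gene Fcer1g rose by 6.43 and Cd160 by 3.63, whereas the cytotoxic genes Gzma (-8.13) and Prf1 (-4.79) fell. This list was not past the threshold with all libraries (median 2.34; camera adjusted p = 0.0813) and was past it without Runx3-positive replicate 2 (adjusted p = 0.0448) or Runx3-negative replicate 3 (adjusted p = 0.0357). ILC2 genes went both ways, 5 rising, 3 falling and 2 not passing out of 10, also when adjusted over the list alone (camera adjusted p = 0.643). The nuclear receptor gene Rora (1.92) and Hs3st1 (4.46) were higher and the receptor gene Il9r (-6.50) and Bmp7 (-3.85) lower.

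T-lineage genes were lower in Runx3-positive cells. Of 29 regulators and pre-T cell receptor signalling genes, 0 rose, 26 fell and 3 did not pass, with 27 falling when adjusted over the list alone. Ly6d fell from 12.02 ± 0.42 to 1.95 ± 0.56, and Bcl11b, a T cell commitment factor, by 8.16. The median was -2.85 (camera adjusted p = 1.83e-19, and adjusted p = 0.0123 with an estimated correlation). Of 19 genes of CD4 CD8 double-positive thymocytes, 0 rose, 18 fell and 1 did not pass, with 19 falling when adjusted over the list alone. Some of these genes, such as Ly6d, are also in the list of regulators and signalling genes. Arpp21 went from 12.11 ± 0.29 to 2.08 ± 0.49, and the list median was -8.03 (camera adjusted p = 2.72e-19, and adjusted p = 0.0123 with an estimated correlation). Although cells with surface CD3 had been excluded from both populations, 8 of 11 CD3 and T cell receptor constant genes fell, 1 rose and 2 did not pass, as they did when adjusted over the list alone. Cd247, the zeta chain of the receptor complex, fell by 8.46 (median of the list -7.85; camera adjusted p = 5.64e-06, and adjusted p = 0.0162 with an estimated correlation). The member that rose, Trgc1 (13.07 ± 0.52 to 15.81 ± 0.34), encodes a gamma chain constant region, and reads of the near-identical Trgc genes, like those of Trbc1 and Trbc2, are uncertain in their assignment.

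Genes of gamma-delta T cells were split, with 3 of 14 higher, 6 lower and 5 not past the threshold, and 4 higher and 6 lower when adjusted over the list alone (camera adjusted p = 0.607). Il17re rose by 3.71, and Trdc (-7.14) and the scavenger receptor gene Scart2 (-6.10) fell. Of 8 Notch target genes, 1 rose, 4 fell and 3 did not pass, as they did when adjusted over the list alone. Notch3 fell from 8.02 ± 0.59 to 1.80 ± 0.78, and Dtx4 rose by 3.17. The Notch list had a camera adjusted p of 0.0662 with all libraries, and 0.0496, 0.0468 and 0.0497 without Runx3-positive replicate 1, 2 or 5. Lineage transcription factors numbered 14 higher, 12 lower and 8 not past the threshold among 34, and 15 and 13 when adjusted over the list alone. Their median was 0.39, their mean -0.12, and the camera adjusted p 0.993. Zbtb7b, which encodes ThPOK, went from 1.58 ± 0.09 to 7.40 ± 0.25, and Id3 from 11.25 ± 0.34 to 5.89 ± 0.52. Genes tied to RUNX3 in other lymphocytes were also divided, 5 of 12 higher, 4 lower and 3 not past the threshold, and 6 and 5 when adjusted over the list alone (camera adjusted p = 0.828). The integrin gene Itgae (-3.90) and Cd8a (-10.02) were lower, and Cd160 (3.63) was higher.

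Of 25 cytokine receptors, 13 rose, 8 fell and 4 did not pass, also when adjusted over the list alone (camera adjusted p = 0.253). Il1r1 and Il23r rose, and Il9r and Il10ra (-5.73) fell. Of 25 chemokine receptors, integrins and homing genes, 11 rose, 4 fell and 10 did not pass, with 11 and 5 when adjusted over the list alone (camera adjusted p = 0.101). Gpr183, an oxysterol receptor, rose from 7.09 ± 0.53 to 11.76 ± 0.39, while Ccr9 (-9.02) and Sell (-7.42), the receptors for thymus and lymph node entry, fell.

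**Figure D2:**
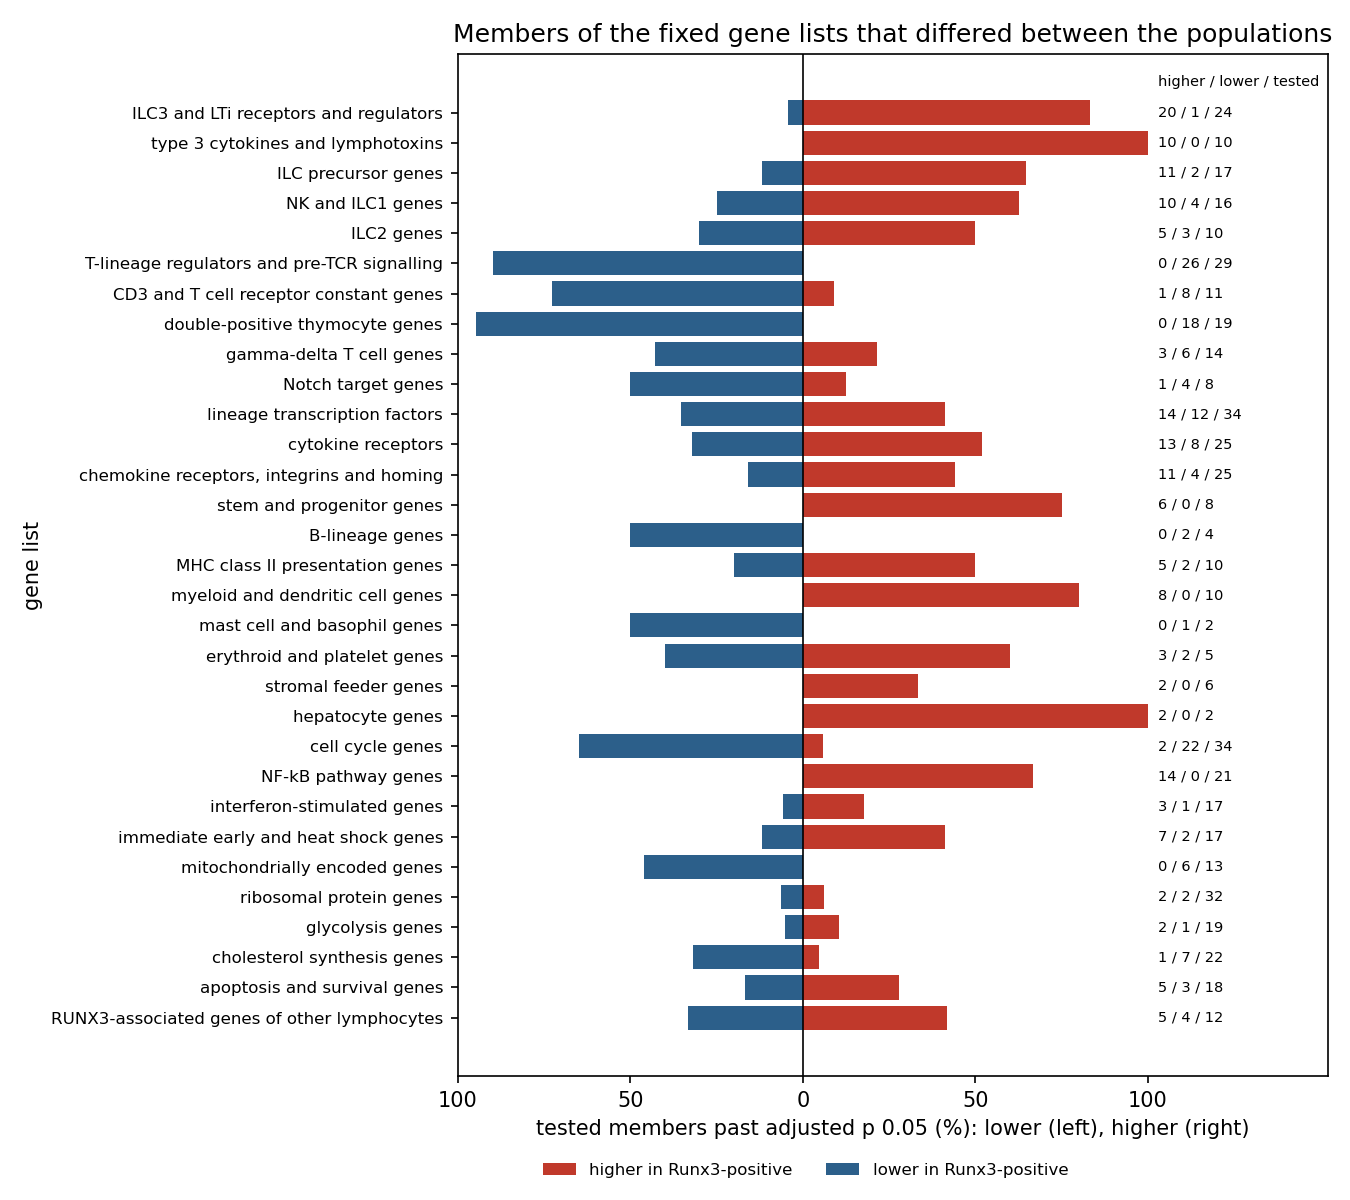
Share of the tested members of each of 31 gene lists that were higher (right) or lower (left) in Runx3-positive than in Runx3-negative libraries at an adjusted p below 0.05, in percent, with the numbers higher, lower and tested printed at the right. All 10 tested type 3 cytokines and lymphotoxins were higher, and 18 of 19 tested double-positive thymocyte genes were lower.

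Cell division genes were lower in Runx3-positive cells, with 2 of 34 cell cycle genes rising, 22 falling and 10 not passing, also when adjusted over the list alone. The mitotic genes Bub1b (-1.96) and Kif11 (-1.78) fell, and the G1 cyclin genes Ccnd2 (2.02) and Ccne1 (1.17) rose. The median was -1.12 (camera adjusted p = 3.17e-07, and adjusted p = 0.291 with an estimated correlation). NF-kB pathway genes rose, 14 of 21 with 0 falling and 7 not passing, and 15 when adjusted over the list alone. Relb went from 7.39 ± 0.26 to 9.88 ± 0.22 and Bcl3 from 1.59 ± 0.40 to 6.76 ± 0.97 (median of the list 1.15; camera adjusted p = 1.22e-05, and adjusted p = 0.0311 with an estimated correlation). Of 17 immediate early and heat shock genes, 7 rose, 2 fell and 8 did not pass, also when adjusted over the list alone (camera adjusted p = 0.123), with Jun (3.35) and Junb (1.84) among those higher and Btg2 (-1.23) among those lower. Of 17 interferon-stimulated genes, 3 rose, 1 fell and 13 did not pass, also when adjusted over the list alone (camera adjusted p = 0.755). Isg20 rose by 1.33 and Ifit2 fell by 1.28. Apoptosis and survival genes went both ways, 5 of 18 higher, 3 lower and 10 not past the threshold, also when adjusted over the list alone (camera adjusted p = 0.735). Bcl2 (2.67) and Bax (2.18) rose, and Fas (-3.05) fell.

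Lists of metabolic and housekeeping genes were examined as well. Of 22 cholesterol synthesis genes, 1 rose, 7 fell and 14 did not pass, also when adjusted over the list alone. Fdft1 fell by 1.09 and Dhcr7 by 1.48, and Ebp rose by 0.71. The list median was -0.38 (camera adjusted p = 0.0456, and adjusted p = 0.502 with an estimated correlation). The cholesterol call was lost without any one of Runx3-positive replicates 2, 3, 4 and 5 (adjusted p of 0.0755, 0.0556, 0.0552 and 0.0622) and of Runx3-negative replicates 2 and 4 (0.0843 and 0.0844). Of 13 mitochondrially encoded genes, 0 rose, 6 fell and 7 did not pass, also when adjusted over the list alone. The genes mt-Atp6 (-1.90) and mt-Cytb (-0.53) fell, and the median was -0.49 (camera adjusted p = 0.0456, and adjusted p = 0.588 with an estimated correlation). The mitochondrial call was lost without Runx3-positive replicate 3 (adjusted p = 0.179) or 4 (0.0854), or without Runx3-negative replicate 2 (0.0557) or 4 (0.0766). Without Runx3-positive replicates 3 and 4 together, 3 of the 13 genes rose and 5 fell (camera adjusted p = 0.813). Of 32 ribosomal protein genes, 2 rose, 2 fell and 28 did not pass, and 0 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.658). Of 19 glycolysis genes, 2 rose, 1 fell and 16 did not pass, and 1 rose and 0 fell when adjusted over the list alone. Hk2 rose by 2.05, with an adjusted p in limma of 0.00872 that became 0.067 without Runx3-positive replicates 3 and 4, and the glycolysis list had a median of -0.04 but a mean of 0.25 (camera adjusted p = 0.993).

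Genes of progenitors and of other cell types were examined as well. Of 20 stem and progenitor genes, 4 were listed at 0 in all libraries and 8 were tested. Of the 8, 6 rose, 0 fell and 2 did not pass, and 7 rose when adjusted over the list alone. Without a filter on low values, 6 of 16 rose (camera adjusted p = 0.000475). Mef2c went from 1.75 ± 0.09 to 8.06 ± 0.38 and Cd93 from 6.84 ± 1.04 to 11.14 ± 0.39 (median of the list 3.36; camera adjusted p = 6.16e-05, and adjusted p = 0.0427 with an estimated correlation). Of 24 myeloid and dendritic cell genes, 6 were listed at 0 in all libraries and 10 were tested. Of the 10, 8 rose, 0 fell and 2 did not pass, and 9 rose when adjusted over the list alone. Without a filter on low values, 7 of 18 rose (camera adjusted p = 0.0122). Zbtb46 rose by 4.13, the chemokine receptor gene Xcr1 by 3.68, Irf8 by 2.07 and Lyz2 from 5.33 ± 0.55 to 8.20 ± 1.02 (median of the list 2.47; camera adjusted p = 0.000332, and adjusted p = 0.0481 with an estimated correlation). Of 10 genes of MHC class II presentation, 5 rose, 2 fell and 3 did not pass, also when adjusted over the list alone (camera adjusted p = 0.363). Cd40 (3.82) and the protease gene Ctss (3.45) rose, H2-DMa (-2.40) and H2-DMb2 (-4.07) fell, and H2-Oa was at 7.73 ± 0.52 and 7.94 ± 0.37.

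Lists with few tested members gave smaller counts. Of 5 erythroid and platelet genes, 3 rose and 2 fell, also when adjusted over the list alone, with Car2 (5.72) and Hba-a1 (3.17) higher and Epor (-5.72) and Gata1 (-4.72) lower. The erythroid median was 1.77 and the mean 0.04, while camera ranked the list downwards (adjusted p = 0.993), and reads of Hba-a1 are shared with a near-identical copy. Of 6 stromal feeder genes, 2 rose, 0 fell and 4 did not pass, also when adjusted over the list alone (camera adjusted p = 0.253). Timp3 rose by 4.08 and Cald1 by 2.51, the adjusted p of Cald1 in limma going from 0.0164 to 0.0964 without Runx3-positive replicates 3 and 4, in which stromal transcripts were high. Pdgfrb was at 5.51 ± 2.16 and 5.80 ± 1.07. Of 4 B-lineage genes, 0 rose, 2 fell and 2 did not pass, and 4 fell when adjusted over the list alone. Fcrla (-3.92) and Blk (-4.07) fell, and Ighm was at 12.53 ± 0.59 and 13.20 ± 0.33. Of 2 mast cell and basophil genes, Cpa3 fell by 3.70 and Hdc was at 4.89 ± 0.32 and 4.47 ± 0.47, counts of 0 higher and 1 lower that held when adjusted over the list alone. The adjusted p of Cpa3 in limma was 0.0182 with all libraries, 0.0618 without Runx3-negative replicate 3 and 0.0586 without Runx3-negative replicate 4. Both tested hepatocyte genes rose, also when adjusted over the list alone, Trf from 3.46 ± 1.20 to 9.64 ± 0.21 and Apoa2 by 1.65, but the adjusted p of Apoa2 in limma was 0.0454 with all libraries and between 0.0619 and 0.125 without any one of Runx3-positive replicates 1 to 4 and Runx3-negative replicates 2 and 3.

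The libraries separated by population. The first principal component held 67.6% of the variance and the second 6.88%. Correlations across genes, which are not independent replicates, were between 0.924 and 0.970 among Runx3-positive libraries, between 0.939 and 0.955 among Runx3-negative libraries, and between 0.742 and 0.793 across the populations. The groups did not overlap for 4289 tested genes (32.2%), against 1.59% by chance. The 50 most abundant genes held 13.8% ± 0.416 of the summed linear values in Runx3-positive and 12.3% ± 0.463 in Runx3-negative libraries (exact permutation p = 0.0159, adjusted p = 0.0238 over 3 library measures). Mitochondrially encoded genes held 1.17% ± 0.250 and 1.42% ± 0.0642 (exact permutation p = 0.0159, adjusted p = 0.0238). Runx3-positive replicates 3 and 4, which also held stromal transcripts, stood at 0.812% and 0.989%, against 1.33% to 1.35% in the other 3. The difference in the share of mitochondrially encoded genes, -0.257 percentage points, was -0.169 without replicate 3 and -0.0806 without both, where 3 against 4 libraries allow no exact permutation p below 0.0571. Genes were counted as detected where the deposited log2 value was positive, which need not mean that reads were present. Their numbers were 17640.2 ± 189.7 and 17568.2 ± 150.9 (exact permutation p = 0.619). Counted at a linear value of at least 10, the difference was 250.6 genes (exact permutation p = 0.111).

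Runx3-positive replicate 5 was the only library from its starting fraction. Without it, limma called 4647 genes, and it lay within the range of the other 4 Runx3-positive libraries for 54.9% of them. The same share was between 50.2% and 69.0% for each of those 4 when that library was the one left out. Its correlation across genes with the mean of the other 4 was 0.972, against 0.953 to 0.973 for the others. With replicate 5 as a group of its own and the spread taken from the other 8 libraries, on the assumption that it varies like them, limma called 0 genes between it and the other 4, and 377 had an unadjusted p under 0.05. The same fit for each of the other 4 in turn called 0 to 7 genes higher and 0 to 18 lower, with 219 to 1045 at an unadjusted p under 0.05. In simulated data of this design 38 of 50 genes with a log2 difference of 4 were recovered and 18 of 50 with one of 2, but only 4 of 50 with one of 1 and 0 of 50 with one of 0.5. Against the Runx3-negative libraries, 1067 genes were higher and 857 lower in replicate 5 in limma, against 1162 to 1600 and 883 to 1477 for the others. This fit was chosen after the data had been examined.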

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

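The tests of Runx3-positive replicate 1 were chosen after its values had been seen, as was the use of Y-linked genes as a covariate and the fit without Runx3-positive replicates 3 and 4. For 18 of 214 sets of libraries examined, 1 library stood far from the others of its group, where chance gives about 1 in 20, or 10.7. Levels in parentheses are log2 values.

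Runx3-positive replicate 1 stood apart for 5 genes. It was high for Rorc (16.39, others 15.18 to 15.48), Gzma (11.01, others 3.81 to 5.49), H2-DMb2 (4.471, others 0.21 to 0.78) and Egr1 (8.645, others 7.17 to 7.35), and low for Ighm (11.48, others 12.71 to 12.87). Runx3-positive replicate 2 was low for Xcr1 (7.576). Runx3-positive replicate 3 was low for Cd160 (13.33) and Rpl32 (13.11). Runx3-positive replicate 5 was low for Chad (9.851) and high for Bub1b (10.25) and Eno1 (16.19). Runx3-negative replicate 4 was high for Hmgn3 (5.97), Il23r (6.791) and Cald1 (1.505). The remaining cases were low Trgc1 in Runx3-negative replicate 1 (12.3), low Cd93 (5.29) and Isg20 (8.611) in replicate 2, and high Bcl3 in replicate 3 (2.192).

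The difference between the populations was set against other splits of the same libraries. Of 100 splits into 5 and 4 libraries, only the real one, 1 split, called as many as 4967 genes in limma, and 95 called none. Splits that mix the populations put their difference into the spread within groups, so few calls were likely there. The splits also cannot speak to chance differences between animals or cultures. The highest of the others, 2111 genes, set Runx3-positive replicates 1 to 4 against the other 5 libraries and so moved a single library. A different mix of male and female embryos was tested because the mean of 4 Y-linked genes ranged from 3.59 to 10.39 across libraries, and 94.7% of the called genes kept their call with that mean as a covariate, which argues against it as the whole cause. Starting fraction stays open, since no fraction gave libraries of both populations.

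T cell receptor transcripts and Gzma in Runx3-positive replicate 1 were weighed as 2 parts. Carry-over of cells like those of the Runx3-negative libraries would bring their abundant transcripts together. For comparison, 18 pre-T cell receptor and double-positive genes were taken. They were chosen for a linear Runx3-negative level of at least 1000 and a fall of at least 6 in these data, which favours low shares. Their median share was 0.262% of the Runx3-negative level, against 2.11% for Cd3d, Cd3g, Trbc1 and Trbc2, which were not chosen so. Trbc2 had a share of 19.6% with little excess in replicate 1, and Cd3g one of 0.194%. The receptor comparison therefore does not decide on carry-over. Gzma, which also fell by more than 6, had a share of 12.8%, far above the highest of the 18, 2.86% for Myb. A higher floor for genes with few reads may account for the receptor part, where the median excess of the 4 genes over the other 4 libraries was 1.21 and the 18 genes reached 1.31, although Cd3d (2.24) and Trbc1 (3.50) exceeded that and Cd3g (-0.34) and Trbc2 (0.17) showed little or no excess. It cannot account for Gzma, with an excess of 6.46. The floor test was also run on 3 genes picked for their excess after the first result (Gzma, Trbc1 and Cd3d, smallest excess 2.24), a choice that would by itself reverse the first result and is given no weight. Cells of another kind with high Gzma stay open, although the sort for CD45, RORγt and Runx3 without surface CD3 and CD19 would be expected to remove T cells and cells lacking RORγt, and no biological explanation was tested.

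Stromal transcripts were high in Runx3-positive replicates 3 and 4, with Col1a1 at 6.48 and 6.30 and Col3a1 at 7.74 and 7.63. Carry-over of feeder cells may explain this, since 15 of 19 stromal feeder genes other than Col1a1 were higher in both libraries than in each of the other 7, where chance gives 2.78% per gene, and the genes are not independent. Of the 15, Ccn2 (-0.20 and -0.39), Lox (0.77 and 0.56), Serpinh1 (1.48 and 1.41), Fbn1 (2.09 and 2.40), Postn (2.99 and 2.91) and Pdgfra (3.17 and 2.89) lay below the filter value of 3.32 in both libraries. Of the 4 genes not higher in both, Sparc (7.26 and 7.34) and Pdgfrb (5.08 and 2.68) were higher in replicate 1, at 7.79 and 8.56. The sort for CD45 would be expected to remove such cells, Dll4 was listed at 0 in all libraries, and stromal cells of the fetal liver were not told apart from the feeder line. Without these libraries 2426 genes were higher and 2112 lower in limma, and the adjusted p of the mitochondrially encoded list was 0.813.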

How the results depend on the processing

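Alternatives with the Y-linked covariate, without Runx3-positive replicates 3 and 4 together and with 8 libraries without a block were chosen after seeing the data. Under all alternatives run, limma called 2272 to 2908 genes higher and 1909 to 2601 lower, and every gene called with all libraries and still tested kept its direction, 81.3% to 100% keeping their call. Of 102 named genes, 89 kept their call throughout, and over 2233 comparisons 83 calls were lost and 1 was gained. Of 28 lists, 14 kept their side of the threshold, and 24 of 669 comparisons lost a call and 21 gained one. The number of higher lists, 6, became 10 without a filter on low values and 14 with fry, which does not compare a list with other genes, and the number of lower lists, also 6, became 3 with an estimated correlation and was 4 to 7 when single libraries were left out. With the number of genes detected as a covariate the Rorc difference was 0.41 with an adjusted p of 0.0301 in limma, against 0.053 to 0.311 in its other alternatives. The cause was not tested. Without Runx3-positive replicates 3 and 4 together, the difference in the share of mitochondrially encoded genes was -0.0806 percentage points and that of the 50 most abundant genes 1.74, neither of which 3 against 4 libraries could call (smallest exact p 0.0571). Correlations of deviations gave no sign that replicate numbers pair the libraries. They were 0.0401, -0.0420, 0.0454 and -0.0252 for equal numbers, and between -0.0351 and 0.0812 for unequal numbers. Such values cannot exclude shared embryos or cultures, on which the labels are silent. With a replicate block, 2440 genes were higher and 1986 lower, against 2543 and 2104 for the same 8 libraries without it. Count-based tests on recovered reads were not run, because no whole reads could be recovered. Unknown depth limits what can be said of genes with low values.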

Other observations

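Families of genes with a common symbol were compared with all other protein-coding genes tested, a search chosen after the data had been examined, by Fisher's exact test over 70 families and 140 tests. The whole search was repeated with each other scaling and without members of the fixed cell cycle list. Among 39 genes with the symbol Il, which name interleukins and their receptors, 19 rose and 11 fell (adjusted p = 0.0152 for the share that rose, against 22.4% of other genes). Among 57 Cd genes, which name surface antigens, 26 rose and 15 fell (adjusted p = 0.00696 for the share that rose). Among 24 Gpr genes, which name G protein-coupled receptors, 12 rose and 2 fell (adjusted p = 0.0497 for the share that rose). The Gpr call was lost with trimmed-mean or quantile scaling, where 11 rose (adjusted p = 0.0987 and 0.0959), and without members of the cell cycle list (0.0733).

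Among 26 Kif genes, which encode kinesins, 5 rose and 12 fell (adjusted p = 0.0169 for the share that fell, against 17.2% of other genes), and among 29 Cdc genes, a symbol that also covers genes with roles outside cell division, 6 rose and 13 fell (adjusted p = 0.0169). The fixed cell cycle list holds 2 members of each family. Without them 10 of 24 Kif and 12 of 27 Cdc genes fell, against 17.1% of other genes, and over the whole search the Kif call was lost (adjusted p = 0.0713) and the Cdc call was not (0.0297). Of 314 Zfp genes, which encode zinc finger proteins, 36 rose and 58 fell (adjusted p = 5.86e-05 for a share that rose below the 22.9% of other genes), and with quantile scaling 30 rose and 80 fell. Of 53 Eif translation initiation factor genes, 3 rose and 5 fell (adjusted p = 0.0347 for a share that rose below the 22.6% of other genes). The Eif call was lost with trimmed-mean scaling (0.0551) and stood at 0.0498 with quantile scaling. Of 49 Rpl ribosomal protein genes, 7 rose and 1 fell (adjusted p = 0.0377 for a share that fell below the 17.4% of other genes). With quantile scaling 7 Rpl genes rose and 2 fell (0.0498). The 44 Rps genes, also of ribosomal proteins, had no such call, 4 rising and 5 falling (adjusted p = 0.749 for the share that fell). Genes of a family are not independent, so these p-values are too small to that extent.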
